A study of Aspergillus nidulans FGSC A4 with 6 samples.

How the data were processed

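RNA of Aspergillus nidulans wild type was measured on 6 two-colour Agilent gene expression arrays. Per the labels, mycelium was grown for 16 h on 1% fructose and then moved to 1% xylose for 6, 12 or 24 h. The fructose RNA was labelled with Cy3 and the xylose RNA with Cy5 on every array, with 2 biological replicates per time and no dye swap. RNA was extracted with Trizol and cleaned on a column, and 5 µg of it was labelled. The labelling text in the labels speaks of untreated and SEB-treated samples, which is not the design the sample labels give; the sample labels were used.

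Per the file headers, the authors scanned the slides on a GenePix scanner and read them with Agilent Feature Extraction 9.5.3.1. The deposited scanner files give for each spot a mean signal and a local background in each dye, in units of intensity, and a processed intensity after background subtraction and dye normalization. Per the file headers they also give a log10 ratio of processed Cy5 over processed Cy3. The deposited series table holds a score, which was found to be that log10 ratio with the decimal point lost and rounded to 3 digits. After rescaling it correlated with the scanner's ratio at r of 0.999999 on each array, with a largest difference of 0.005. The array has 45220 spots, of which 43803 carry a probe for 1 of 11143 genes and 1417 are controls. Each gene has 1 probe on at least 3 spots. The reference table holds 10443 of these genes, of which 774 have a symbol, and gives no product names. Genes without a symbol are named here by locus identifier and described only by the list they are on.

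The deposited spot names were checked against the repeated spots of each probe. On both 6 h arrays, repeated spots did not resemble each other: the correlation of their Cy3 signals across probes was 0.00102 and -0.00261. It was 0.638 and 0.769 on the 12 h arrays, and 0.975 and 0.985 on the 24 h arrays. The software's own grid check had given a warning status (2) on the slide of the 6 h and 12 h arrays and none (0) on the other. The spot names of each array were therefore realigned to those of 24 h replicate 2. The row and column offset at which Cy3 signals correlated best was found for the whole array. Spots were then put into bins by how far their image position lay from the fitted grid. Each bin took the best of the row offsets around that of the array. A bin needed at least 100 spots, a correlation of at least 0.7 and a margin of 0.3 over other offsets, and spots outside such bins were left out. The grids of both 6 h arrays lay 6 rows off, and that of replicate 1 also 1 column off. On the 12 h arrays 13.0% and 7.88% of the spots received another name, and on the 24 h arrays 0%. Realignment kept 90.5%, 89.4%, 98.2%, 97.0%, 99.99% and 99.98% of the spots, in the order 6, 12 and 24 h with replicate 1 first.

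After realignment, the correlation of Cy3 signals of repeated spots was 0.933, 0.921, 0.961, 0.973, 0.975 and 0.985 in the same order. The median net Cy3 signal of the 153 negative control spots fell from 221 to 0.267 and from 266.4 to -2.17 on the 6 h arrays. Under the deposited names, the 10 spike-in probes of the 6 h arrays correlated with those of 24 h replicate 2 at -0.0300 and 0.518. The decision to realign rested on these quality values, not on ratios of genes, and was taken after the files had been seen. On simulated grids 6 rows and 1 column off with 10% slipped spots, 97.5% of spots received a name and 100% of those names were right. The real 6 h arrays were less clean. In 1 kept bin of replicate 1 the next best offset still correlated at 0.44, against 0.873. The share of right names on those arrays is not known. Realigned names were used for every value unless the deposited names are mentioned.

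Signals were corrected by normexp with an offset of 50 in limma 3.58.1 (R 4.3.3, the data.table package in version 1.17.8), and log2 ratios of xylose over fructose were normalized by loess within each array. Control spots had no weight. Spots the software called non-uniform were dropped, and spots of a probe were averaged. The software's background flags had been planned as the detection filter. They depend on which spots it took for controls, so after the files had been seen they were replaced by the realigned negative controls and kept as an alternative. A gene counted as detected in a dye when its net signal exceeded the median plus 3 median absolute deviations of the realigned negative controls. A gene was tested when it had a value on all 6 arrays and was detected in either dye on at least 2 arrays. This left 8283 genes, of which 716 have a symbol. A further 696 genes lacked a value on some array and 2164 were below the filter. Between 70.4% and 80.4% of the genes were above background in Cy3 and between 70.5% and 75.9% in Cy5, and the number of arrays limits the precision. Where a gene was saturated in one dye or not above background in the other, its fold is given as a lower bound. Alignment and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

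A limma model with 1 mean per time was fitted to the 6 arrays with no replicate block, which leaves 3 residual degrees of freedom. Arrays with the same replicate number appear to share fructose RNA, as described below, so these degrees of freedom are not independent. Each time was tested against fructose and the times against each other, 6 comparisons in all. Tests were two-sided at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The model, the threshold for calls, 25 of the gene lists and 20 alternatives were fixed before the data were examined. A further 12 lists were fixed after the files had been opened but before any ratio of a gene was seen. Lists were compared with all other genes by camera with a preset correlation of 0.01, and p-values were adjusted over the 25 lists with at least 5 measured members and the 6 comparisons, 150 pairs. Of the other lists, 3 had no measured member (cytosolic ribosomal proteins, ribosome biogenesis, and cell cycle and DNA replication) and the rest, sugar regulators among them, were described without a test. Of the 150 pairs 31 passed. With a correlation estimated from the arrays, camera passed 0 of them, and that p is given with each. This version refers to the few residual degrees of freedom and was not tried on simulated lists. Its failure to pass a list therefore decides little. The estimated correlation was 0.776 for pentose catabolism and 0.0868 for xylan degradation, above the preset 0.01, and -0.0983 for the pentose phosphate pathway, below it. The preset version was tried on simulated lists, but only with genes that varied independently. Its p-values may be too small for lists whose members vary together. The directional test fry passed 5, among them xylan degradation at 6, 12 and 24 h (fry adjusted p = 0.0158, 0.0103 and 0.0103).

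The rule for named genes took, for each time against fructose, the 8 highest and 8 lowest genes with an adjusted p under 0.05, one sign in both replicates and a symbol. Between 6 h and 24 h it took 6 and 6, and between other times 3 and 3. It added every member of the pentose catabolism list, every sugar regulator, and up to 4 of the largest passing members of each other list, or the largest member as a value where none passed. The rule was also applied to the blocked model described next; that use, and every other gene without a symbol and not named by the rule, was chosen after the values were seen.

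The labels give each time a replicate 1 and a replicate 2. Across genes, the difference between replicates 1 and 2 at one time correlated with that at another at 0.842 for 6 and 12 h, 0.835 for 6 and 24 h and 0.791 for 12 and 24 h, so the numbers pair the arrays. The pairing comes mainly from the Cy3 dye. The same correlations were 0.881, 0.879 and 0.937 for Cy3 alone, and 0.328, 0.00536 and -0.00420 for Cy5 alone. Each array of one number appears to carry the same fructose RNA, which the labels do not state. A model with the replicate number as a block is given beside each result whose call it changes. It treats the 2 fructose preparations as fixed, so its errors leave out the difference between them. In comparisons between times that difference cancels if the preparations were shared. There the median standard error of a gene was 0.222 without the block and 0.116 with it.

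Unchanged groups were simulated against 2 shared fructose preparations, 100 times, with each gene's own spread between preparations or with that spread shrunk toward that of all genes; the second was added after the first was seen. With own spreads, the unblocked model called 8.41, 8.98 and 8.71 genes on average at 6, 12 and 24 h, and the blocked model 1310, 1320 and 1320. With shrunk spreads the means were 0.75, 0.81 and 0.76 unblocked and 794, 798 and 802 blocked. With shared preparations, the unblocked adjusted p-values of genes against fructose may therefore be too small as well. The unblocked calls at each time are to be read beside these simulated counts. Between times, the unblocked model called 0 and the blocked model at most 0.29 on average. Known changes were also put into simulated arrays. With independent arrays, the unblocked model recovered 50.3% of 2-fold, 87.4% of 4-fold and 97.8% of 16-fold changes at 6 h, with 7.7 false calls per run. With shared preparations of own spread it recovered 60.8%, 85.8% and 94.9%, with 69.4 false calls, and the blocked model 1340 false calls. Between 6 and 24 h, the unblocked model recovered 1.54% of 2-fold, 50.0% of 4-fold and 83.1% of 16-fold changes with shared preparations, with 0 false calls. The blocked model recovered 80%, 99.2% and 100% of them, with 4.3 false calls per run. Unblocked counts of 0 between times may therefore miss changes. Each run held more changed genes than were called on the real arrays, which eases the adjusted threshold. These shares may therefore be too high for the real arrays.

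The alternatives were other background corrections, the scanner's own ratios, the series table, median centring, scaling between arrays, other filters, other variance models, the replicate block, fewer arrays and leaving out each array in turn. Added after seeing the data were the deposited spot names, the median over spots, array weights, the software's background flags, the replicate as a random block, leaving out both 6 h arrays, and Cy5 levels alone. With 1 probe per gene, taking the brightest probe gives no other value. Both 24 h arrays were on another slide than the 6 h and 12 h arrays, with another scanner resolution, so slide and 24 h cannot be told apart.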

Results

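RNA levels of Aspergillus nidulans wild type were compared between mycelium grown on fructose and mycelium moved from fructose to xylose for 6, 12 or 24 h. Each of the 6 arrays held xylose RNA in Cy5 and fructose RNA in Cy3, with 2 arrays at each time. The median net Cy3 signal of the gene spots, in scanner intensity units, was 300.1 and 287.7 at 6 h, 281.5 and 231.7 at 12 h, and 277.1 and 370.6 at 24 h, replicate 1 first. The median net Cy5 signal was 253.8 and 262.2 at 6 h, 193.5 and 284.0 at 12 h, and 70.3 and 107.3 at 24 h. Log2 ratios below are of xylose over fructose, with their standard error, and rest on n = 2 arrays per time. All adjusted p-values of genes are from limma, and those of lists from camera. Those of genes against fructose may be too small, since the arrays of different times appear to share fructose RNA.

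**Figure D1:**
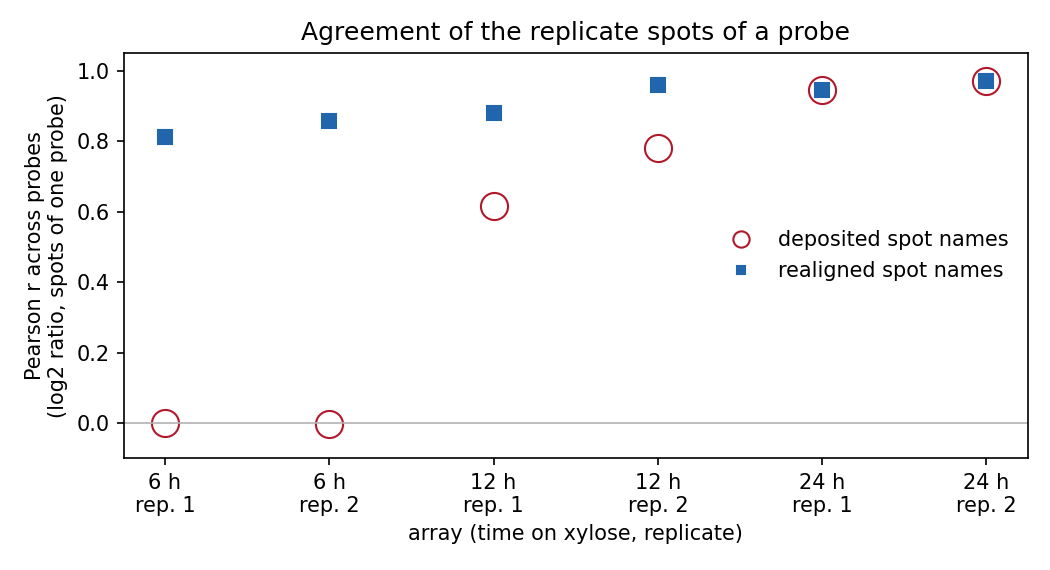
Correlation across probes between the log2 ratios of repeated spots of a probe, for each array, under the deposited and the realigned spot names. On the 6 h arrays it rose from -0.000129 to 0.812 (replicate 1) and from -0.00357 to 0.856 (replicate 2). On the 24 h arrays it stayed at 0.945 and 0.970.

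The xylose and fructose samples were compared at each time to find genes that may respond to xylose, with sugar transporters as the genes the study was after. The labels name no fructose sample of the same age as the xylose samples, and none moved from fructose to fructose. Each ratio of xylose over fructose may therefore also hold effects of the move, the loss of fructose and the age of the mycelium. For the genes and lists below, these cannot be told apart from a response to xylose.

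After 6 h on xylose, 10 genes rose and 0 fell among 8283 tested. Of the 10, 5 belong to xylan degradation, 1 to pentose catabolism, the steps that turn xylose into an intermediate of central metabolism, and 1 to the sugar transporters. xlnD (AN2359), which codes for a beta-xylosidase, rose by 4.97 ± 0.16 (adjusted p = 0.00662, higher on both arrays). The pentose catabolism gene AN0423 was at least 111-fold higher, since its xylose signal was saturated (adjusted p = 0.0459). The transporter AN0250 rose by 5.28 ± 0.20, which is 38.8-fold (adjusted p = 0.00865).

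The xylan degradation list rose as a group at 6 h, with a median log2 ratio of 2.66 over 12 members (adjusted p = 1.79e-10; adjusted p = 0.854 with an estimated correlation). With no filter on dim genes the median was 1.69. Of its members 5 rose and 7 did not pass, and 8 rose when adjusted over the list alone. Besides xlnD these were AN1818 at 6.41 ± 0.25, AN3613 at 4.78 ± 0.32, AN7908 at 4.22 ± 0.27 and AN6093 at 2.53 ± 0.13. aguA (AN9286), an alpha-glucuronidase, had a log2 ratio of 2.79 ± 0.21 and did not pass (adjusted p = 0.0511, 0.0047 with the replicate block). AN9365, another member picked after its values were seen, was at 3.60 ± 0.38 (adjusted p = 0.123, 0.00094 with the block).

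The pentose catabolism list also rose at 6 h, with a median of 1.52 over 6 members (adjusted p = 4.38e-05; adjusted p = 0.854 with an estimated correlation). AN0423 passed over all genes, and 4 members passed when adjusted over the list alone. The others were AN9064 at 3.38 ± 0.63 (adjusted p = 0.273, 0.00094 with the block) and AN8790 at 2.23 ± 0.19 (0.073, 0.0021 with the block). AN10169 was at 0.82 ± 0.14 (0.263, 0.017 with the block), AN0942 at 0.67 ± 0.72 (0.767, 0.033 with the block) and akr1 (AN7193) at -0.06 ± 0.56 (0.979). The sugar transporters had a median of 0.53 over 10 members and rose (adjusted p = 0.0049; adjusted p = 0.854 with an estimated correlation). Across settings that kept the call, the transporter median went from 0.19 with no filter on dim genes to 1.49 with genes detected on all 6 arrays. The call ended with the block (adjusted p = 0.234), with scaling between arrays, and without 6 h replicate 1 (median 0.64, adjusted p = 0.0612). Of the transporters 1 rose and 9 did not pass, and 4 rose when adjusted over the list alone. With the block 4 of them rose and 3 fell. AN8347, picked after its values were seen, had the highest log2 ratio of the transporters at 5.39 ± 0.50 and did not pass (adjusted p = 0.0898, 0.0040 with the block).

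The sugar regulators did not pass at 6 h. xlnR (AN7610), the activator of xylan degradation genes, was at 0.15 ± 0.34 (adjusted p = 0.893), creA (AN6195), the carbon catabolite repressor, at -0.38 ± 0.21 (0.616), AN0388 at -0.02 ± 0.13 (0.969) and AN2016 at -0.47 ± 0.12 (0.344, 0.034 with the block). The sterigmatocystin cluster, genes for a mycotoxin, fell as a group by a median of -0.50 over 16 members (adjusted p = 3.04e-05; adjusted p = 0.854 with an estimated correlation). None of its members passed over all genes, 2 fell when adjusted over the list alone, and 8 fell with the block. Its median was -0.28 without 6 h replicate 1, where the call was lost (adjusted p = 0.0578). It was 0 with the log ratios of the scanner software (Agilent processed log ratios, adjusted p = 0.834) and -0.88 with no background subtraction. Its largest member, AN7806, was at -1.09 ± 0.53 (adjusted p = 0.57, 0.0046 with the block).

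Chaperones rose as a group at 6 h by a median of 0.62 over 11 members (adjusted p = 0.000152; adjusted p = 0.854 with an estimated correlation), 0.39 without 6 h replicate 1. Of them 1 rose when adjusted over the list alone; the largest, hsp78 (AN1163), was at 1.02 ± 0.29 (adjusted p = 0.391). The heat shock and oxidative stress list, which shares 5 members with the chaperones, rose by a median of 0.51 over 10 members (adjusted p = 0.0152; adjusted p = 0.907 with an estimated correlation). That call was lost with the block (adjusted p = 0.120), without 6 h replicate 1 (median 0.21, adjusted p = 0.296), with the Agilent processed log ratios (median 0.25) and with scaling between arrays. Its member AN0858 was at least 3.46-fold higher, with a saturated xylose signal, and did not pass (adjusted p = 0.121, 0.0075 with the block). Ribosome assembly factors rose by a median of 0.39 over 25 members (adjusted p = 0.0158; adjusted p = 0.999 with an estimated correlation), but by 0.01 without 6 h replicate 2 (adjusted p = 0.996) and 0.93 without replicate 1. The median was 0.18 with the Agilent processed log ratios, where the call was lost, and up to 0.72 with other filters. None of their members passed over all genes or over the list alone, 11 rose with the block, and cbf5 (AN8851) was at 1.53 ± 1.23 (adjusted p = 0.721, 0.0046 with the block). With the block, nitrogen metabolism (median 0.92, adjusted p = 0.303 without and 0.0334 with it) and ribosomal proteins and translation initiation (median 0.25, 0.124 without and 0.0400 with it) also passed, though not with the block and an estimated correlation (adjusted p = 0.733 for each). Without 6 h replicate 2 their medians were 0.03 and -0.08.

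The remaining genes called at 6 h, on no list and picked after their values were seen, were AN7864 at 5.02 ± 0.22, AN1477 at 4.76 ± 0.13 and AN8522 at 2.53 ± 0.13. With the replicate block 1800 genes passed, 921 higher and 879 lower. The named gene with the highest ratio in that model was gcy1 (AN1274), at least 13.2-fold higher (adjusted p = 0.226, 0.0010 with the block). gatA (AN2248), a GABA transaminase, was at 1.68 ± 0.43 (0.344, 0.0098), aspf13 (AN6273) at 1.66 ± 0.42 (0.344, 0.0047). niaD (AN1006) and niiA (AN1007), the nitrate and nitrite reductases, were at 1.43 ± 0.95 (0.683, 0.0060) and 1.41 ± 0.85 (0.647, 0.0050). The lowest were fdh (AN6525), a formate dehydrogenase, at -1.92 ± 0.72 (0.465, 0.0063), fgaCat (AN5918), a catalase, at -1.72 ± 0.47 (0.356, 0.0029), and treA (AN9340), a trehalase, at -1.41 ± 0.41 (0.393, 0.011). aspf2 (AN1832) was at -1.38 ± 0.26 (0.281, 0.021) and cyn1 (AN7331), a cyanase, at -1.25 ± 0.75 (0.647, 0.0050). gel2 (AN0558) was at -1.20 ± 0.26 (0.292, 0.017), ccpA (AN10109) at -1.18 ± 0.90 (0.71, 0.0040) and afeA (AN0054) at -1.17 ± 0.51 (0.529, 0.0084).

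Simulated unchanged groups that shared 2 fructose preparations gave 8.41 calls at 6 h on average and at most 27, or 0.75 and at most 5 with shrunk spreads, and with the block 1310 or 794. The count of 10 fell to 0 without either 6 h array or either 12 h array and to 6 without either 24 h array, and with scaling between arrays it was 0.

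**Figure D2:**
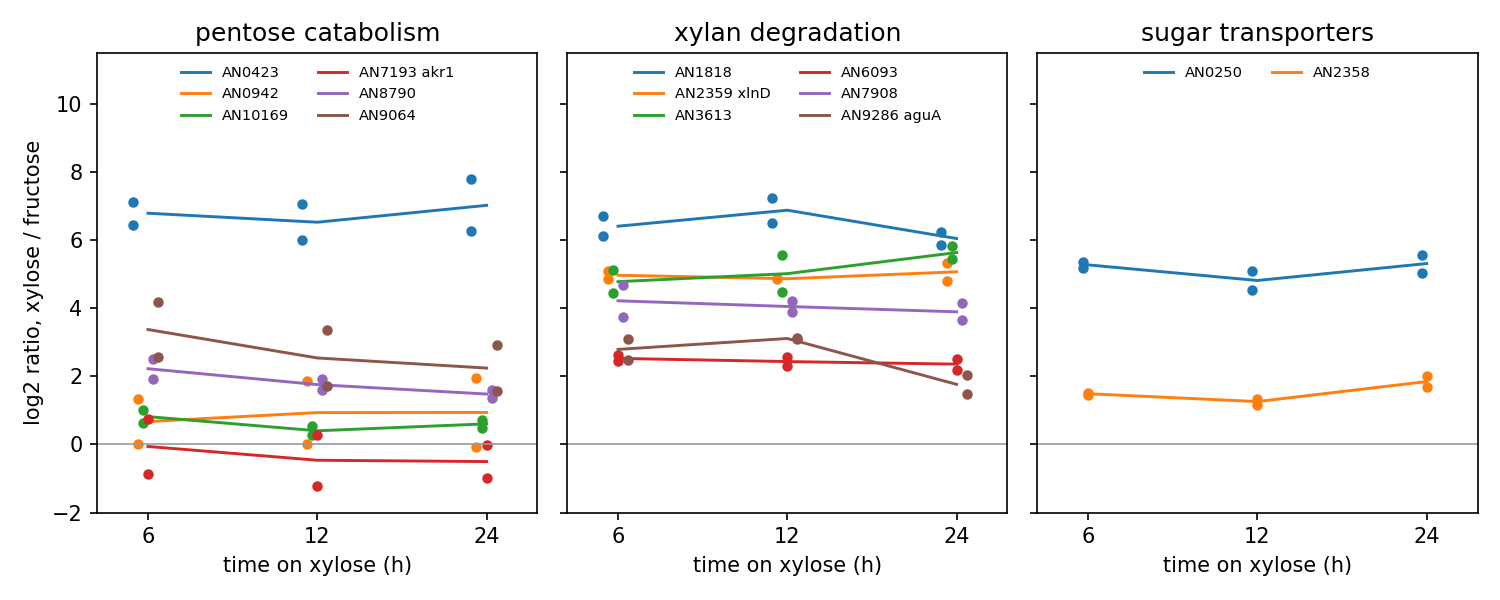
Log2 ratios of xylose over fructose against time on xylose (h) for the pentose catabolism genes, the called xylan degradation genes and the called sugar transporters, with points for arrays and lines for the mean of 2 arrays. The transporter AN0250 was at 5.28, 4.82 and 5.32 at the 3 times.

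After 12 h on xylose, 12 genes rose and 3 fell. The 10 genes that had risen at 6 h were again called, with aguA at 3.11 ± 0.21 (adjusted p = 0.0344) and AN9287 at 4.73 ± 0.32 (adjusted p = 0.0344) in addition. xlnD was at 4.87 ± 0.16 (adjusted p = 0.00727) and the transporter AN0250 at 4.82 ± 0.20, which was higher on both arrays (adjusted p = 0.0108). AN0423 was at least 92.4-fold and the xylan degradation gene AN1818 at least 118-fold higher, both with saturated xylose signals. The 3 genes that fell were AN2387 at -2.17 ± 0.17, AN8609 at -1.83 ± 0.13 and AN5468 at -1.46 ± 0.09. These and AN9287 are on no list and were picked after their values were seen. With the replicate as a random block, 11 genes were called higher at 12 h and 0 lower, so the 3 falls were lost.

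The xylan degradation list rose at 12 h by a median of 2.77 over 12 members (adjusted p = 4.23e-10; adjusted p = 0.854 with an estimated correlation). With no filter on dim genes the median was 1.60. Of its members 6 rose, 7 when adjusted over the list alone, with AN3613 at 5.02 ± 0.32, AN7908 at 4.05 ± 0.27 and AN6093 at 2.44 ± 0.13. The pentose catabolism list rose by a median of 1.35 (adjusted p = 0.00104; adjusted p = 0.907 with an estimated correlation), with 1 of 6 members passing and 3 when adjusted over the list alone. It did not pass without 12 h replicate 1 (median 0.93, adjusted p = 0.0583) or with scaling between arrays. AN9064 was at 2.54 ± 0.63 (adjusted p = 0.284, 0.0010 with the block), AN8790 at 1.76 ± 0.19 (0.0855, 0.0032 with the block), AN0942 at 0.94 ± 0.72 (0.664, 0.016 with the block), AN10169 at 0.40 ± 0.14 (0.384) and akr1 at -0.46 ± 0.56 (0.784).

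The sugar transporters rose at 12 h by a median of 0.76 (adjusted p = 0.0158; adjusted p = 0.854 with an estimated correlation), with 1 of 10 members passing, 3 when adjusted over the list alone, and with the block 4 higher and 3 lower. It did not pass with the block (adjusted p = 0.312), without 12 h replicate 1 (median 0.63, adjusted p = 0.134), and with no filter on dim genes (median 0.26, adjusted p = 0.090). The Agilent processed log ratios, scaling between arrays and keeping outlier spots also ended the call. The sterigmatocystin cluster fell by a median of -0.50 (adjusted p = 0.000228; adjusted p = 0.886 with an estimated correlation), with 0 members passing, 2 when adjusted over the list alone and 9 with the block. Without 12 h replicate 1 its median was -0.28 (adjusted p = 0.122), and settings that kept the call gave -0.32 with no filter on dim genes, -0.94 with no background subtraction and -1.21 with the Agilent processed log ratios. Its largest member, AN7806, was at -1.09 ± 0.53 (adjusted p = 0.505, 0.0040 with the block). With the block, ribosome assembly factors (median 0.50, adjusted p = 0.0896 without and 0.000142 with it) and peroxins (median -0.15, 0.28 without and 0.0303 with it) passed, though not with the block and an estimated correlation (adjusted p = 0.733 for each). Both medians turned without 12 h replicate 2, to -0.15 and 0.06. The sugar regulators did not pass: xlnR was at -0.03 ± 0.34 (adjusted p = 0.984), creA at -0.05 ± 0.21 (0.941), AN0388 at 0.00 ± 0.13 (0.993) and AN2016 at -0.49 ± 0.12 (0.284, 0.029 with the block).

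With the block 2005 genes passed at 12 h, 1013 higher and 992 lower. The highest named genes of that model were ivoB (AN0231) and ivoA (AN10576), which act in conidiophore pigment formation, at 3.21 ± 1.52 (adjusted p = 0.499, 0.0067 with the block) and 1.69 ± 0.84 (0.512, 0.047). ags2 (AN5885), an alpha-1,3-glucan synthase, was at 3.20 ± 1.04 (0.353, 0.0032), gcy1 at 3.11 ± 0.56 (0.222, 0.0017), agdC (AN0941) at 2.14 ± 0.67 (0.346, 0.0059) and aspf13 at 1.90 ± 0.42 (0.252, 0.0040). The lowest were treA at -2.07 ± 0.41 (0.231, 0.0055), mfsA (AN9168) at -1.77 ± 0.97 (0.552, 0.0044), fgaCat at -1.64 ± 0.47 (0.319, 0.0032), afeA at -1.28 ± 0.51 (0.43, 0.0070), and aspf2 at -1.24 ± 0.26 (0.249, 0.026). gprC (AN3765) was at -1.24 ± 0.36 (0.329, 0.0062), bna4 (AN5200) at -1.12 ± 0.16 (0.173, 0.0084), and tpcL (AN11017), at least 2.16-fold lower (0.369, 0.0035).

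Simulated unchanged groups gave 8.98 calls at 12 h on average and at most 29, or 0.81 and at most 5 with shrunk spreads, and with the block 1320 or 798. The count of 15 fell to 0 without either 12 h array, to 3 without either 6 h or either 24 h array, and to 1 with scaling between arrays.

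After 24 h on xylose, 18 genes rose and 5 fell. xlnD was at 5.07 ± 0.16 (adjusted p = 0.00604), the pentose catabolism gene AN0423 at 7.03 ± 0.47 (adjusted p = 0.0232) and the transporter AN0250 at 5.32 ± 0.20 (adjusted p = 0.00958), all higher on both arrays. A second transporter, AN2358, rose by 1.85 ± 0.12 (adjusted p = 0.0225). AN12137 was at 5.76 ± 0.28 (adjusted p = 0.0154). AN8609 fell by -2.59 ± 0.13 (adjusted p = 0.0154), and AN0759, AN11381, AN10318 and AN7214 were at -1.95 ± 0.12, -1.61 ± 0.13, -1.60 ± 0.11 and -1.23 ± 0.09. AN12137 and the 5 genes that fell are on no list and were picked after their values were seen.

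The xylan degradation list rose at 24 h by a median of 2.06 over 12 members (adjusted p = 2.41e-05; adjusted p = 0.854 with an estimated correlation). With no filter on dim genes the median was 0.99. Of its members 5 rose, 7 when adjusted over the list alone, with AN1818 at 6.05 ± 0.25, AN3613 at 5.64 ± 0.32, AN7908 at 3.90 ± 0.27 and AN6093 at 2.36 ± 0.13. aguA was at 1.77 ± 0.21 (adjusted p = 0.0662, 0.0065 with the block). The pentose catabolism list rose by a median of 1.21 (adjusted p = 0.0061; adjusted p = 0.907 with an estimated correlation), with 1 of 6 members passing and 4 when adjusted over the list alone. It did not pass without 24 h replicate 1 (median 1.04, adjusted p = 0.0973) or with scaling between arrays. AN9064 was at 2.25 ± 0.63 (adjusted p = 0.184, 0.0013 with the block), AN8790 at 1.48 ± 0.19 (0.0682, 0.0027 with the block), AN0942 at 0.94 ± 0.72 (0.481, 0.011 with the block), AN10169 at 0.61 ± 0.14 (0.156, 0.021 with the block) and akr1 at -0.50 ± 0.56 (0.612, 0.039 with the block).

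The sugar transporters rose at 24 h by a median of 1.30 (adjusted p = 0.0152; adjusted p = 0.854 with an estimated correlation), with 2 of 10 members passing and 4 when adjusted over the list alone. With the block the list did not pass (adjusted p = 0.252), nor did it with no filter on dim genes (median 0.52, adjusted p = 0.101), with scaling between arrays or with outlier spots kept, and the median was 0.83 with median centring. AN8347 was at 5.33 ± 0.50 (adjusted p = 0.0537, 0.0026 with the block). With the block 6 transporters rose and 3 fell. The pentose phosphate pathway fell by a median of -0.71 over 6 members (adjusted p = 0.0291; adjusted p = 0.854 with an estimated correlation), with 4 lower and 1 higher when adjusted over the list alone. Neither the block (adjusted p = 0.0501) nor leaving out 24 h replicate 1 (median -0.76, adjusted p = 0.109) kept that call, and it was lost with normexp with offset 0, the Agilent processed log ratios and scaling between arrays. The median was -0.46 without replicate 2. Its largest member, AN5907, was at -0.96 ± 0.38 (adjusted p = 0.279, 0.0039 with the block).

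The sterigmatocystin cluster fell at 24 h by a median of -0.78 over 16 members (adjusted p = 3.45e-05; adjusted p = 0.854 with an estimated correlation), or -0.68 with 6 members at their bounds. The median was -1.37 with normexp with offset 0 and -1.46 with the Agilent processed log ratios, and median centring ended the call. None of them passed over all genes, 4 fell when adjusted over the list alone and 11 with the block; AN7809 was at least 2.24-fold lower (adjusted p = 0.236, 0.0026 with the block). Chaperones rose by a median of 0.52 (adjusted p = 0.0263; adjusted p = 0.928 with an estimated correlation). They did not pass without 24 h replicate 2 (median 0.24, adjusted p = 0.0613) and with median centring (median 0.06, adjusted p = 0.668), nor with the Agilent processed log ratios or scaling between arrays. Their largest member, hsp78, was at 0.91 ± 0.29 (adjusted p = 0.222). The heat shock and oxidative stress list, which shares members with the chaperones, did not pass at 24 h. Its median was between 0.26 and 0.45 across settings. Ribosome assembly factors rose by a median of 0.69 over 25 members (adjusted p = 0.0134; adjusted p = 0.999 with an estimated correlation), with 0 members passing and 16 higher with the block. Their median turned to -0.19 without 24 h replicate 2 (adjusted p = 0.392) and was 1.59 without replicate 1. It was 1.09 with normexp with offset 0, about 1.2 with the Agilent processed log ratios and 0.46 with scaling between arrays, where the call was lost; cbf5 was at 1.56 ± 1.23 (adjusted p = 0.491, 0.0028 with the block). Proteasome subunits fell by a median of -0.24 over 15 members (adjusted p = 0.0120; adjusted p = 0.999 with an estimated correlation), but by -0.03 without 24 h replicate 2 (adjusted p = 0.423) and -0.38 without replicate 1. The median was -0.80 with median centring and -0.14 with scaling between arrays, and the call was lost with the Agilent processed log ratios. Their largest member, pre9 (AN1757), was at -0.56 ± 0.17 (adjusted p = 0.208, 0.0096 with the block). With the block, peroxins passed (median -0.41, adjusted p = 0.186 without and 0.0228 with it), but not with the block and an estimated correlation (adjusted p = 0.733), and the median was -0.04 without 24 h replicate 2.

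The sugar regulators did not pass at 24 h: xlnR was at -0.21 ± 0.34 (adjusted p = 0.723), creA at -0.34 ± 0.21 (0.423), AN0388 at -0.21 ± 0.13 (0.435) and AN2016 at -0.70 ± 0.12 (0.107, 0.0099 with the block). Other genes that rose, on no list and picked after their values were seen, were AN7864 at 4.97 ± 0.22, AN1477 at 4.27 ± 0.13, AN12286 at 3.16 ± 0.19, AN5942 at 3.05 ± 0.24, AN1240 at 2.63 ± 0.22, AN8522 at 2.21 ± 0.13 and AN2249 at 1.48 ± 0.13. AN1568 was at least 6.53-fold and AN7883 at least 3.63-fold higher, their fructose signals not being above background. With the block 3317 genes passed, 1671 higher and 1646 lower. Its highest named genes were gcy1 at 2.98 ± 0.56 (adjusted p = 0.122, 0.0015 with the block), abaA (AN0422), a regulator of conidiation, at 2.32 ± 0.23 (0.0539, 0.0026), and ags2 at 2.02 ± 1.04 (0.362, 0.0038). prnD (AN1731), a proline use gene, was at 1.91 ± 0.34 (0.113, 0.0079), aspf13 at 1.82 ± 0.42 (0.156, 0.0029) and loc1 (AN6556) at 1.32 ± 0.81 (0.419, 0.0039). Its lowest were treA at -1.50 ± 0.41 (0.18, 0.0060), gprC at -1.49 ± 0.36 (0.162, 0.0033), fgaCat at -1.45 ± 0.47 (0.221, 0.0027) and mfsA at -1.45 ± 0.97 (0.444, 0.0039). fdh was at -1.28 ± 0.72 (0.391, 0.0082), cyn1 at -1.28 ± 0.75 (0.403, 0.0033), afeA at -1.16 ± 0.51 (0.316, 0.0057) and faa4 (AN6014) at -1.15 ± 0.37 (0.216, 0.0043).

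Simulated unchanged groups gave 8.71 calls at 24 h on average and at most 35, or 0.76 and at most 5 with shrunk spreads, and with the block 1320 or 802. The count of 23 fell to 0 without either 12 h array, to 6 without either 6 h array, to 4 and 3 without 24 h replicates 1 and 2, and to 0 with scaling between arrays. Median centring, under which the median of all genes was -0.19 against -0.0103, gave 1339 calls, 509 higher and 830 lower against 18 and 5.

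**Figure D3:**
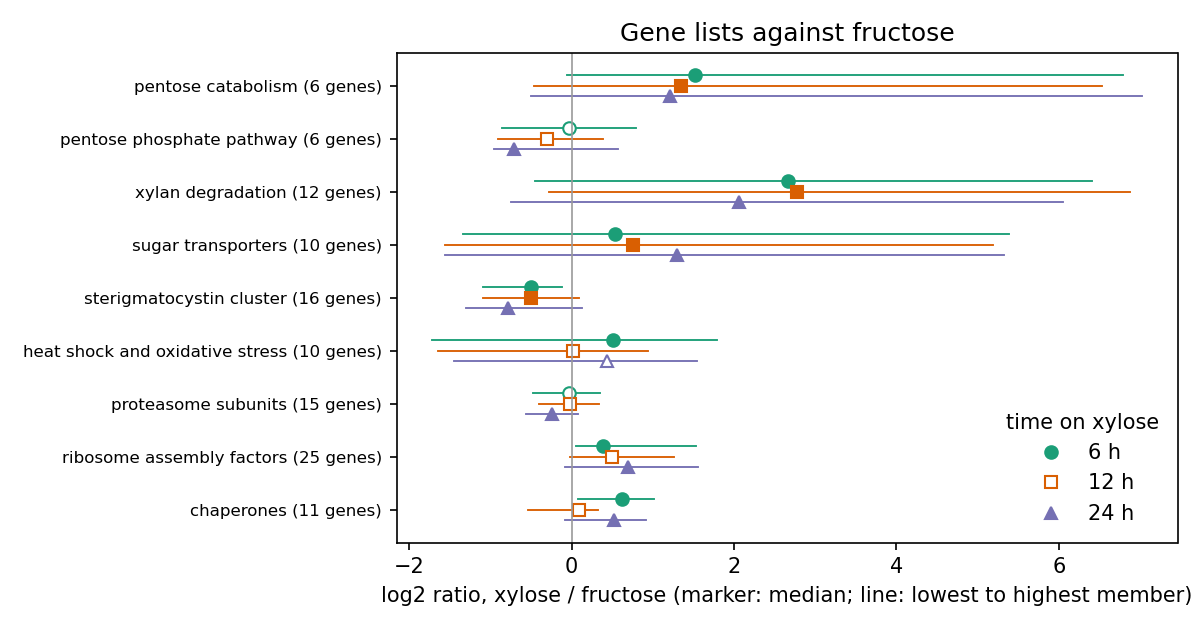
Median log2 ratio of xylose over fructose of 9 gene lists at 6, 12 and 24 h, with bars from the lowest to the highest member and filled points where camera gave an adjusted p under 0.05. The xylan degradation median was 2.66, 2.77 and 2.06, and that of the sterigmatocystin cluster -0.50, -0.50 and -0.78.

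At all 3 times together, 10 genes were called higher and 0 lower, and independent lists would share 3.15e-05 higher genes. They are xlnD, AN1818, AN3613, AN7908 and AN6093 of xylan degradation, AN0423 of pentose catabolism, the transporter AN0250, and AN7864, AN1477 and AN8522 of no list. With the block 1171 genes shared a direction at all 3 times. Unchanged groups with shared fructose preparations gave 6.14 such genes on average and at most 19, or 0.49 and at most 5 with shrunk spreads. With log2 ratios as large as the smallest of the 10 genes (2.21) they gave 1.38 and at most 6, or 0.11 and at most 1. Across genes, which are not independent replicates, log2 ratios correlated at 0.841 between 6 and 12 h, 0.815 between 6 and 24 h and 0.764 between 12 and 24 h, against a simulated mean of 0.884 or 0.784. The covariances were 0.179, 0.210 and 0.205, against a simulated 0.102 or 0.0487. The differences, which estimate the shared effect together with any dye effect, were 0.0769, 0.108 and 0.103, or 0.130, 0.162 and 0.156. With 2 fructose preparations the controls could not be split, so part of the excess may come from the shared controls. Fructose RNA was in Cy3 on every array, so a dye effect of a gene cannot be removed. It would enter the calls at each time and the genes shared by all 3 times, and the simulation held none. Arrays of different times and different replicate numbers correlated at 0.324 on average, and those with the same number at 0.790.

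Between 6 and 12 h on xylose, chaperones fell by a median of -0.60 over 11 members (adjusted p = 3.94e-08; adjusted p = 0.854 with an estimated correlation), -0.37 without 6 h replicate 1. The heat shock and oxidative stress list fell by -0.56 (adjusted p = 9.65e-05; adjusted p = 0.854 with an estimated correlation). It did not pass without 6 h replicate 1 (-0.25, adjusted p = 0.13), without 12 h replicate 2 (-0.32, adjusted p = 0.122) or with the Agilent processed log ratios (-0.18). The largest member of both lists, hsp78, differed by -1.28 ± 0.42 (adjusted p = 1.00). Pentose catabolism fell by a median of -0.41 (adjusted p = 0.0438; adjusted p = 0.938 with an estimated correlation), with AN9064 at -0.84 ± 0.88 and AN8790 at -0.47 ± 0.27 (adjusted p = 1.00 for each). That median was 0.02 without 6 h replicate 1 (adjusted p = 0.94) and 0.13 without 12 h replicate 2 (adjusted p = 0.958). It was -0.69 without 6 h replicate 2 and -0.74 without 12 h replicate 1. The list did not pass without 24 h replicate 1 (adjusted p = 0.0775) or 2 (adjusted p = 0.0714). Its call was also lost with the Agilent processed log ratios (-0.10), no background subtraction, scaling between arrays, no filter on dim genes, and fewer arrays. Trehalose and mannitol genes fell by a median of -0.34 over 5 members (adjusted p = 0.0181; adjusted p = 0.854 with an estimated correlation). They did not pass with the block (adjusted p = 0.0793) or without 6 h replicate 1 (-0.16, adjusted p = 0.296), 12 h replicate 1 (-0.40, adjusted p = 0.0841) or 12 h replicate 2 (-0.21, adjusted p = 0.147). The median was -0.52 without 6 h replicate 2, and median centring ended the call. Siderophore and iron genes rose by a median of 0.18 over 11 members (adjusted p = 0.0120; adjusted p = 0.928 with an estimated correlation). The list did not pass without 6 h replicate 1 (0.16, adjusted p = 0.205) or 12 h replicate 2 (-0.02, adjusted p = 0.485), and its median was 0.38 without 12 h replicate 1 and 0.10 with outlier spots kept. The Agilent processed log ratios ended the call (0.07).

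The largest siderophore and iron gene, mirB (AN8540), a siderophore transporter, differed by 1.27 ± 0.53 between 6 and 12 h (adjusted p = 1.00), and the trehalase gene treA by -0.66 ± 0.58. With the block, nitrogen metabolism (median -0.24, adjusted p = 0.113 without and 0.0228 with it), mitochondrial protein import (-0.14, 0.563 and 0.0462), conidiation and conidial cells (0.11, 0.0896 and 0.0219) and iron uptake (0.22, 0.0896 and 0.0286) passed. None of the 4 passed with the block and an estimated correlation (adjusted p = 0.733 for each). The first 2 medians turned without 6 h replicate 2, to 0.21 and 0.29, and without 12 h replicate 1, to 0.20 and 0.26. In limma 0 genes were called between 6 and 12 h, and 93 had an unadjusted p under 0.05. With the block 0 genes were called as well (553 unadjusted), and each transporter and xylan degradation gene was among those not called.

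Between 12 and 24 h on xylose, chaperones rose by a median of 0.46 over 11 members (adjusted p = 0.00217; adjusted p = 0.905 with an estimated correlation) and the heat shock and oxidative stress list by 0.46 over 10 members (adjusted p = 0.0109; adjusted p = 0.907 with an estimated correlation). Both calls were lost without 12 h replicate 2 (0.28, adjusted p = 0.0926, and 0.22, adjusted p = 0.345) and with median centring (0.06 and 0.05), and that of heat shock and oxidative stress also with the Agilent processed log ratios. The chaperone median was 0.70 and 0.29 without 24 h replicates 1 and 2. Proteasome subunits fell by a median of -0.22 over 15 members (adjusted p = 0.00227; adjusted p = 0.995 with an estimated correlation). They did not pass without 12 h replicate 1 (-0.15, adjusted p = 0.209) or 24 h replicate 2 (-0.04, adjusted p = 0.518), and the median was -0.40 without 24 h replicate 1 and -0.68 with median centring. The Agilent processed log ratios ended the call. The sterigmatocystin cluster fell by a median of -0.28 over 16 members (adjusted p = 0.0265; adjusted p = 0.931 with an estimated correlation). That median was 0.03 without 12 h replicate 2 (adjusted p = 0.735) and 0.01 without 24 h replicate 1 (adjusted p = 0.544), -0.51 without 12 h replicate 1 and -0.50 without 24 h replicate 2, and with no background subtraction it was 0.08. It was -0.67 with normexp with offset 0, and the call was lost with the Agilent processed log ratios, median centring (-0.15), scaling between arrays (-0.11) and outlier spots kept.

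The largest members between 12 and 24 h were hsp78 at 1.17 ± 0.42, pup1 (AN2085) of the proteasome at -0.42 ± 0.34 and AN7817 of the sterigmatocystin cluster at -0.50 ± 0.15 (adjusted p = 1.00 for each). With the block, ribosome assembly factors (median 0.28, adjusted p = 0.266 without and 0.00415 with it) and mitochondrial protein import (0.33, 0.467 and 0.0136) passed. Neither did so with the block and an estimated correlation (adjusted p = 0.754 and 0.733). The medians turned without 24 h replicate 2, to -0.62 and -0.32, and without 12 h replicate 1, to -0.37 and -0.15, and that of mitochondrial protein import was -0.08 with median centring. In limma 0 genes were called between 12 and 24 h, and 320 had an unadjusted p under 0.05. With the block 6 genes were called, picked after their values were seen. AN3983 rose by 3.56, AN12137 by 3.25, AN1568 by 2.87, AN7883 by 2.18 and AN9186 by 2.05, and AN3858 fell by -1.56, with blocked standard errors between 0.09 and 0.19 and blocked adjusted p between 0.0361 and 0.0495. For AN1568 and AN7883, whose fructose signals were not above background, these differences are uncertain. In Cy5 alone only AN3983 passed, at 3.74 (adjusted p = 0.00743). AN12137 was at 3.02 (0.187), AN1568 at 1.96 (0.187), AN7883 at 1.59 (0.179), AN9186 at 2.33 (0.431) and AN3858 at -1.42 (0.431). Simulated unchanged groups gave 0.29 blocked calls on average and at most 4.

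Between 6 and 24 h on xylose, the pentose phosphate pathway fell by a median of -0.47 over 6 members (adjusted p = 0.000468; adjusted p = 0.854 with an estimated correlation), with tktA (AN0688), a transketolase, at -0.77 ± 0.26 (adjusted p = 1.00). The median was -0.90 with median centring, and the call was lost with the Agilent processed log ratios. Iron uptake genes rose by a median of 0.36 over 6 members (adjusted p = 0.0201; adjusted p = 0.854 with an estimated correlation), with AN5823 at 0.86 ± 0.53. That call was lost without 6 h replicate 1 (0.29, adjusted p = 0.171) or 24 h replicate 2 (0.17, adjusted p = 0.422), with median centring (0.17) and with the Agilent processed log ratios (0.58). The median was 0.55 with normexp with offset 0. Proteasome subunits fell by a median of -0.20 over 15 members (adjusted p = 0.0120; adjusted p = 0.999 with an estimated correlation), with rpt3 (AN2904) at -0.34 ± 0.21. That call was lost without 6 h replicate 1 (-0.04, adjusted p = 0.814) or 24 h replicate 2 (-0.01, adjusted p = 0.912), and the median was -0.34 without 6 h replicate 2, -0.35 without 24 h replicate 1 and -0.60 with median centring. It was also lost with normexp with offset 0 and with the Agilent processed log ratios. The sterigmatocystin cluster, with a median of -0.20, did not pass (adjusted p = 0.113). It did under some settings, such as the Agilent processed log ratios (-1.38) and normexp with offset 0 (-0.56). With the Agilent processed log ratios its 6 h median was 0, and whether those 6 h ratios are measured values was not tested. With the block, siderophore and iron genes passed (median 0.19, adjusted p = 0.0551 without and 0.0223 with it), but not with the block and an estimated correlation (adjusted p = 0.733). Their median was -0.06 without 24 h replicate 2.

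No list for xylan degradation, pentose catabolism or sugar transport passed between 6 and 24 h (adjusted p = 0.0896, 0.199 and 0.592). The xylan degradation list, with a median of -0.25, did pass with no background subtraction (-0.51), genes detected on all 6 arrays (-0.34), the software's background flags (-0.34) and without 6 h replicate 1 (-0.30). Pentose catabolism, at -0.33, passed without 6 h replicate 2 (-0.72). AN9365 of xylan degradation differed by -1.15 ± 0.54, AN9064 of pentose catabolism by -1.13 ± 0.88, AN8790 by -0.74 ± 0.27 and the transporter AN6412 by 1.66 ± 0.51 (adjusted p = 1.00 for each). In limma 0 genes were called between 6 and 24 h, and 292 had an unadjusted p under 0.05. With the block 3 genes rose, picked after their values were seen: AN12137 by 4.67 ± 0.13 (blocked adjusted p = 0.0067), AN3983 by 4.29 ± 0.19 (0.0230) and AN1568 by 2.97 ± 0.15 (0.0322). The fructose signal of AN1568 was above background on 0 arrays. In Cy5 alone AN12137 was at 4.59 (adjusted p = 0.0348) and AN3983 at 4.66 (0.00206), while AN1568 was at 2.09 and did not pass (0.0955). Simulated unchanged groups gave 0.15 blocked calls on average and at most 3, and both 24 h arrays were on another slide than the rest.

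**Figure D4:**
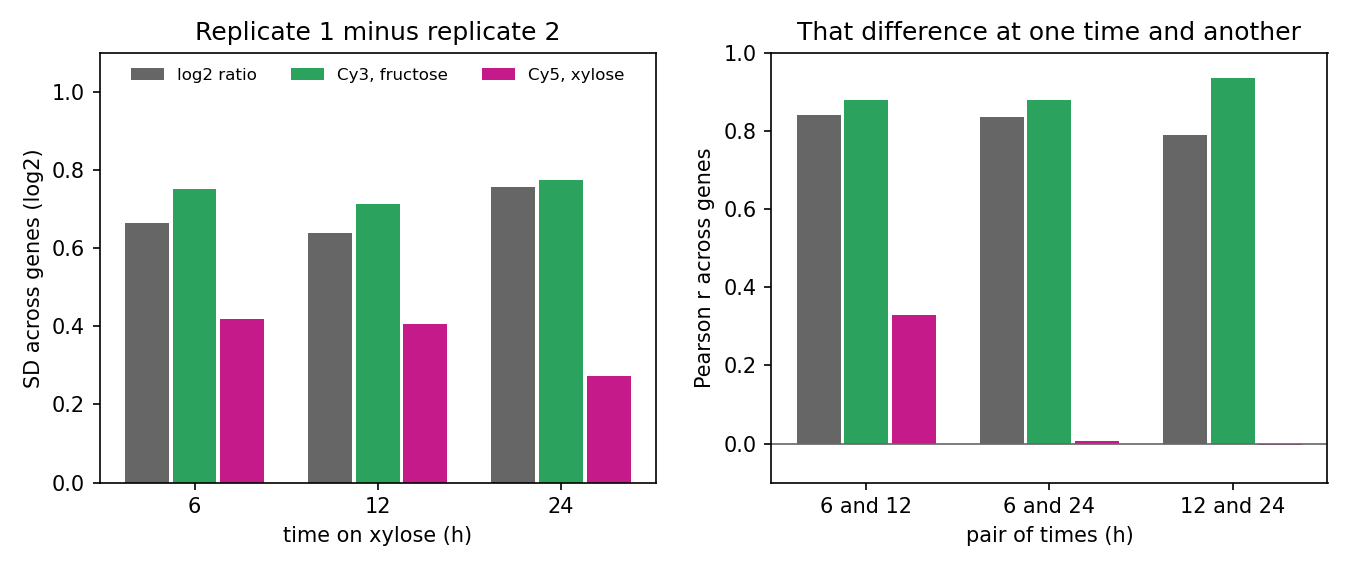
Standard deviation across genes of the difference between replicates 1 and 2 (log2) at each time for the log ratio and each dye, and correlation of those differences between times. For Cy3 the standard deviation was 0.752, 0.714 and 0.775, against 0.418, 0.406 and 0.272 for Cy5.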

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

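All tests of explanations in this part were chosen after the result was seen. The values here were picked out because a test of the difference between times passed, for genes in the model with the replicate block and for lists in camera without it.

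AN12137, AN3983 and AN1568, which are on no list, were higher after 24 h than after 6 h on xylose by 4.67, 4.29 and 2.97 on the log2 scale with the replicate block (limma adjusted p = 0.0067, 0.0230 and 0.0322), against 0.386, 0.898 and 0.386 without it. Their median Cy3 change over their median Cy5 change was -0.0174, which decides nothing about an effect of slide or scan on both dyes, since the genes were picked for their ratio, where such an effect cancels. Their Cy5 levels differed by 4.59, 4.66 and 2.09, with limma adjusted p = 0.0348, 0.00206 and 0.0955 for Cy5 alone, and AN1568 was above background in Cy3 on 0 arrays. An effect of slide or scan and a later response to xylose cannot be told apart, since 0 arrays of another time were on the slide of the 24 h arrays. A later response may therefore hold, as an untested explanation, and it cannot be told apart from an effect of the age of the mycelium.

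The genes that differed between 12 and 24 h with the block were AN3983 by 3.56 (limma adjusted p = 0.0377), AN12137 by 3.25 (0.0361), AN1568 by 2.87 (0.0377), AN7883 by 2.18 (0.0495), AN9186 by 2.05 (0.0495) and AN3858 by -1.56 (0.0495). Without the block each of the 6 had an adjusted p of at least 0.542. In Cy5 alone only AN3983 passed, with a difference of 3.74 (limma adjusted p = 0.00743). The other 5 had adjusted p between 0.179 and 0.431, among them AN1568 at 1.96 and AN7883 at 1.59. The fructose signals of AN1568 and AN7883 were not above background at 24 h, so their differences in log ratio are uncertain.

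Between 6 and 12 h the median log2 difference was -0.41 for pentose catabolism, -0.34 for trehalose and mannitol, -0.56 for heat shock and oxidative stress, 0.18 for siderophore and iron genes and -0.60 for chaperones. Between 12 and 24 h it was -0.28 for the sterigmatocystin cluster, 0.46 for heat shock and oxidative stress, -0.22 for proteasome subunits and 0.46 for chaperones. Between 6 and 24 h it was -0.47 for the pentose phosphate pathway, 0.36 for iron uptake and -0.20 for proteasome subunits. With an estimated correlation none of these 12 differences passed in camera (adjusted p of at least 0.854). Leaving out 1 array ended the call for each of them except chaperones between 6 and 12 h and the pentose phosphate pathway between 6 and 24 h.

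The log ratios of replicates 1 and 2 differed in the same way at all 3 times. A difference between the fructose preparations, each used on the 3 arrays of its number, fits this: the Cy3 replicate differences of the 3 pairs of times correlated across genes at 0.899 on average. For Cy5 the correlations of 24 h with 6 h and 12 h were 0.00536 and -0.00420, which argues against a history of the xylose cultures of one number that holds at 24 h. Between 6 and 12 h, which were on 1 slide, it was 0.328, and a history shared by those cultures stays open. Misplaced spots are argued against by the 24 h arrays, whose spots were in place and whose log ratios still correlated at only 0.465 (genes are not independent replicates in any of these correlations). The labels do not say how the fructose cultures differed, and no biological explanation was tested.

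Under the deposited spot names, the 6 h log ratios were unrelated to those of 12 and 24 h. A grid lying off the printed spots on both 6 h arrays fits this, since repeated spots of a probe correlated across probes at 0.812 or more after realignment. A different state of the mycelium at 6 h is argued against as the cause, since it would leave repeated spots alike, and under the deposited names they correlated at -0.000129 at most. Of the 10 genes called at 6 h, 7 had the other sign under the deposited names.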

How the results depend on the processing

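The alternatives added after seeing the data were the deposited spot names, array quality weights, the median over spots, the software flags in the filter, the random block, leaving out both 6 h arrays, and Cy5 levels alone. Counts of calls stayed within 1.5 times in 127 cases and moved further in 76. Of the values of single genes 5789 kept direction and call, 160 became and 193 ceased to be calls, 678 with no call moved, and 0 calls changed sign. The deposited spot names were run for counts only and are not among these; under them 7 of the 10 genes called at 6 h had the other sign. Values with no call did change sign for some genes, such as xlnR (AN7610) at 6 h, which ranged from -0.30 to 0.59, and akr1 (AN7193) at 12 h, from -1.21 to 0.28. Of the list results 2860 kept both, 120 became and 172 ceased to be calls, 402 moved, and in 10 the test pointed the other way. These 10 each had a call in the main fit or under the alternative. Other list medians also changed sign, such as that of ribosome assembly factors at 12 h, which went down to -0.15. The cause was not tested unless one is named.

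In the order 6, 12 and 24 h, the calls were 10, 15 and 23. They were 4, 7 and 48 with the Agilent processed log ratios and also with the series matrix values, 0, 1 and 0 with scale normalization between arrays, and 6, 7 and 8 with eBayes with trend and robust. With only the arrays of the times compared they were 0, 0 and 0, where fewer arrays leave 1 residual degree of freedom. With slide 1 alone they were 6 at 6 h and 3 at 12 h, and with both 6 h arrays left out 3 at 12 h and 6 at 24 h, again with fewer arrays. Spot names as deposited gave 0, 29 and 54. Array quality weights gave 16 at 6 h, and no filter on dim genes 9 at 12 h and 37 at 24 h. At 24 h, normexp with offset 0 gave 155, median centring in place of loess 1339, and outlier-flagged spots kept 51. Leaving out 1 array gave between 0 and 6 calls at 6 h, 0 and 3 at 12 h, 0 and 6 at 24 h, and 0 and 0 between times; the time with 1 array left was assumed to vary like the others.

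Genes called in the same direction at all 3 times numbered 10. They were 4 with the Agilent processed log ratios, 4 with the series matrix values, 0 with scale normalization between arrays, 6 with eBayes with trend and robust, 0 with only the arrays of the times compared, 0 with spot names as deposited, and between 0 and 3 with 1 array left out. Between times, spot names as deposited gave 9 calls from 6 to 12 h and 16 from 6 to 24 h, and Cy5 levels alone gave 1 from 12 to 24 h and 2 from 6 to 24 h.

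The replicate numbers pair the arrays mainly through the fructose dye. The replicate block gave 1800, 2005 and 3317 calls at 6, 12 and 24 h, 6 from 12 to 24 h, 3 from 6 to 24 h and 1171 at all 3 times. It removes the difference between the fructose preparations from the error, and unchanged groups simulated with shared preparations gave 1310, 1320 and 1320 blocked calls. The replicate as a random block gave 6 calls from 12 to 24 h and 5 from 6 to 24 h. The replicate block kept all 10, 15 and 23 calls made without it, and the random block kept 9, 9 and 19 of them. Apart from the calls given beside their results, the replicate block changed no other call of a list.

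Of the 150 pairs of list and comparison 31 passed. The number was 19 with the Agilent processed log ratios, 19 with the series matrix values, 0 for camera with an estimated correlation, 5 for fry, directional, and between 32 and 37 with 1 array left out. With slide 1 alone it was 16 and with both 6 h arrays left out 17, each of 75 pairs, since these hold only 3 of the comparisons; 16 of the same 75 pairs passed with all arrays in either case. The test pointed the other way for pentose catabolism from 6 to 12 h with the Agilent processed log ratios (median -0.10) and the series matrix values (-0.11). It did so for the sterigmatocystin cluster from 6 to 12 h with each (-1.21, adjusted p = 1.37e-07, and -1.21, adjusted p = 1.36e-07). With the Agilent processed log ratios that cluster had a median of 0 at 6 h and -1.21 at 12 h. Its difference therefore has the size of its 12 h median. Whether the 6 h ratios of 0 are measured values was not tested. The test also pointed the other way without 24 h replicate 2 for ribosome assembly factors at 24 h, from 12 to 24 h and from 6 to 24 h. Their medians with 1 array left out ranged from -0.19 to 1.59, -0.62 to 1.24 and -0.66 to 1.14. From 6 to 12 h it did so for peroxins without 6 h replicate 1 (range -0.35 to 0.35) and amino acid biosynthesis without 12 h replicate 2 (-0.30 to 0.36), and from 12 to 24 h for ribosomal proteins and translation initiation without 12 h replicate 2 (-0.29 to 0.29).

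Signal over background limits the values of dim genes: between 70.4% and 80.4% of the genes were above background in Cy3 and between 70.5% and 75.9% in Cy5. Choosing the brightest probe of a gene gives no value, since each gene has 1 probe.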

Other observations

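Lists other than those above had 0 members called at any time in limma. In nitrogen metabolism, 11 members measured, the median log2 ratio was 0.92, 0.04 and 0.55 at 6, 12 and 24 h (camera adjusted p = 0.303, 0.988 and 0.307). Of its members, prnD of proline use differed between 12 and 24 h by 1.76 ± 0.48 (adjusted p = 1.00). Starch degradation, with 3 members and not tested, was at -0.50, -0.39 and -0.78; its member AN8953 was at -2.08 ± 0.36, -2.25 ± 0.36 and -2.25 ± 0.36 (adjusted p = 0.263, 0.205 and 0.0963, or 0.0010, 0.00092 and 0.00086 with the replicate block), lower on 2 of 2 arrays at each time. The 3 penicillin cluster members had a median of -0.10, -0.24 and 0.60, and 3 of 3 were higher at 24 h when adjusted over the list alone; AN2622 was at 0.69 ± 0.13 (adjusted p = 0.122). Gluconeogenesis, glyoxylate cycle and acetate or ethanol use (10 members) was at 0.01, -0.28 and -0.42 (adjusted p = 0.91, 0.936 and 0.607), with a mean of -0.29 against its median and test at 6 h, and AN0554 at -2.28 ± 1.01, -1.78 ± 1.01 and -2.41 ± 1.01.

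Cellulose degradation (8 members) had medians of -0.06, -0.08 and -0.19 at 6, 12 and 24 h (camera adjusted p = 0.601, 0.771 and 0.315), with a mean of 0.06 against its median and test at 12 h. Glycolysis (10) was at -0.17, -0.04 and -0.04 (0.432, 0.996 and 0.996; mean 0.06 at 24 h), conidiation and conidial cells (15) at -0.03, 0.07 and 0.08 (0.939, 0.432 and 0.811; mean 0.09 at 6 h), and cell wall synthesis and remodelling (23) at -0.08, -0.21 and -0.17 (0.124, 0.265 and 0.170). Ergosterol and mevalonate biosynthesis (17) was at 0.02, -0.03 and 0.03 (0.946, 0.996 and 0.941; mean 0.15 at 12 h), amino acid biosynthesis (18) at 0.23, 0.18 and 0.12 (0.404, 0.352 and 0.940), and mitochondrial protein import (8) at 0.16, 0.00 and 0.33 (0.852, 0.881 and 0.695), the last -0.17 with median centring. Other secondary metabolite backbone enzymes (5) were at -0.01, 0.04 and 0.16 (0.778, 0.596 and 0.996), and pectin and rhamnogalacturonan genes with symbols (5) at 0.02, -0.04 and -0.04 (0.905, 0.936 and 0.881). Lists too small for a test were at 0.08, 0.05 and 0.12 for pectin and arabinan degradation (3), -0.02, -0.39 and -0.21 for the TCA cycle and respiratory chain (1), and -0.61, -0.60 and -0.67 for fatty acid beta-oxidation (1). Autolysis (4) was at -0.36, -0.42 and -0.08, sexual development (2) at -0.04, 0.16 and -0.07, and autophagy genes (4) at -0.13, -0.11 and -0.18.

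The test in this paragraph was chosen after the result was seen. Changes between 6 and 24 h may be shared by neighbouring genes: the change of a gene correlated with that of the next gene on the chromosome at 0.2224 over 7858 genes, which are not independent replicates, against at most 0.0431 in 10000 permutations of the order (permutation p = 1e-04, the smallest they can give). The run of 7 neighbours with the highest mean difference went from AN7893 to AN7898, with a mean of 2.75. At 24 h its member AN7893 was at 0.39 in replicate 1 and 6.24 in replicate 2, and AN7894 at 0.46 and 6.15. Their 24 h ratios were thus high in replicate 2 only. Averaged over the 3 times, their Cy3 levels differed between the replicates by 2.32 and 2.73. In Cy5 alone these genes rose by 3.73 and 4.27 between 6 and 24 h, so their change is not confined to the fructose dye. The correlation of neighbouring genes was 0.148 for the Cy3 difference between the replicates, which holds no xylose signal. Against fructose it was 0.127, 0.144 and 0.167 at 6, 12 and 24 h. Between times it was 0.109 for 6 and 12 h and 0.2231 for 12 and 24 h. Sharing by neighbours is thus not particular to the change between 6 and 24 h. The highest values, 0.2231 and 0.2224, compare arrays of different slides.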
